A study of Mus musculus with 2 samples.

How the data were processed

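H3K4me3 ChIP-seq of mouse heart at embryonic day 13.5 was available as peak lists of 2 biological replicates, both from pooled male and female embryos, which form 1 group. Per the labels, the peaks are placed on mm10, and the 2 samples give different biosample labels and the same donor label, so it is not known whether their embryos were collected separately. Per the submitters' file list, the peaks of each replicate were called from its filtered alignments and 1 control file, and the pooled peaks from the alignments of both replicates and 2 control files. Every replicated peak was also a peak of the pooled list. The peak caller, its version, the filters on alignments and the rule for the replicated set are not given in the sources used here. Of the pooled peaks 28332 overlapped a peak of both replicates over 50% of either peak, and all of these were in the replicated set, while 1999 replicated peaks had no such overlap. The deposited fold of each peak is read here as a ratio of immunoprecipitated to control DNA, from its place in the narrowPeak format and its range of values, as no source used here defines it. The deposited p-value and q-value of each peak are −log10 values, and the smallest −log10 p was 2.06 in replicate 1 and 2.01 in replicate 2, so the lists hold weak peaks. Of the replicates' peaks 70.4% and 71.5% had a −log10 q of at least 5. No file gave read counts, so the depth per sample and the precision it would give are unknown. Aligned reads and signal tracks were not analysed here, and no list of problem regions was used to remove peaks.

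Peaks on chromosomes 1 to 19, X and Y were compared with GENCODE mouse release 21 (GRCm38, the sequence of mm10), from which 21829 protein-coding genes, each symbol counted once, and 54355 start sites of their coding transcripts were taken. A gene was marked where a peak lay within 1000 bp of one of its start sites. Its fold value was the highest of those peaks. Its domain was the widest run of peaks there, joined across gaps of at most 1000 bp. The CpG content of a gene was the highest observed/expected ratio within 500 bp of any of its coding start sites, from the RefSeq sequence of GRCm38.p6. That start site need not be the one with the peak. Coordinates are given counting from 1.

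The 27 gene lists, the tests and the alternatives were fixed before the data were examined. They cover cell types of the heart, cell types that a dissection could bring along and other tissues as a contrast. The rest are lists of housekeeping, the cell cycle, energy metabolism, ribosomal proteins and the Hox clusters. Together 496 members were named one by one, of which 1 (Ahsp) was not annotated, and 4 lists were taken from patterns of gene symbols. Peaks shared between replicates were those covered over at least 50% of their length by peaks of the other replicate, set against 100 shuffles of the peaks within their chromosome, assembly gaps included (one-sided permutation test, smallest p 0.0099). Start sites were compared with shuffles in the same way. List marking was tested with Fisher's exact test, two-sided, against all other protein-coding genes. Domain width was tested, two-sided, against 10000 random lists of marked genes of the same size (smallest unadjusted p 0.0002) for the 24 lists with at least 5 marked members. Both were adjusted over lists by Benjamini-Hochberg with a threshold of 0.05. Replicates were compared by the median log2 ratio of fold values, replicate 2 over replicate 1, less that of all genes marked in both, and its percentile among 10000 random lists matched on mean fold value in 10 bins. Where another measure took the place of fold value, the random lists were matched on the mean of that measure instead. Members marked in 1 replicate only were compared with exact McNemar tests. Correlations were computed across genes.

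The genes named were fixed by a rule. It took the protein-coding gene nearest to the centre of each of the 20 widest domains, the 10 genes of highest fold value, up to 4 marked members per list with the widest domains and up to 5 members without a peak in alphabetical order. It also took the 5 genes with the largest difference between replicates in each direction, list members marked in 1 replicate only, the 5 strongest peaks more than 10000 bp from any start site, and Nkx2-5, Tbx5, Gata4, Myh6, Myh7, Nppa, Wt1, Gata1, Alb, Pou5f1 and Actb. Some were left out for length. Hba-x, Hbb-y, the non-coding genes other than those nearest to distant peaks, the receptor genes and the genes of the Y chromosome fall outside the rule and were chosen after their values were seen.

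The alternatives were stricter peaks (a −log10 q or a fold value of at least 5), windows of 0 and 2500 bp, only the 5'-most start site of each gene, pooled peaks, the peaks of each replicate alone, other overlaps (1 bp, 50% of both peaks, joined peaks, equal numbers of peaks), peaks not joined or joined across 3000 bp, CpG-matched lists in 10 bins, and fold value times width or ranks for the replicate comparison. Added after the data were examined were lists without genes that have another coding start site within 5000 bp, matching on fold value and CpG content together, and domain widths in the replicate comparison. An added list of erythroid genes, sharing none with the one above, was written before its values were seen.

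The procedures were tested on simulated data with 24 genes per list drawn from the 21829 genes. List marking recovered 84 of 100 lists set to 97% marked and called 5 of 400 unchanged lists. Domain width recovered 69 of 100 lists made 1.5 times as wide and called 5 of 400 unchanged ones. The replicate difference was simulated without matching on fold value and with 1 spread for all genes. It put 94 of 100 lists lowered by 0.3 on the log2 scale below percentile 2.5, and 15 of 400 unchanged ones, with the upper side not counted. It therefore does not cover the matched comparison used below or a wider scatter of weak peaks. Interval operations gave the answer of a direct search in 4264 of 4264 cases. The work used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9.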

Results

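The series measured H3K4me3, the trimethylation of histone H3 at lysine 4 that lies at gene promoters, in the hearts of mouse embryos at embryonic day 13.5. Chromatin was immunoprecipitated from pooled male and female embryos of the B6NCrl strain and sequenced, in 2 biological replicates of 1 group, with no second tissue, stage or condition. The deposited values were lists of peaks, the stretches of the genome where the immunoprecipitated DNA exceeded the control DNA, each with a value read here as a fold over that control, which no source used here defines. Replicate 1 had 35997 peaks and replicate 2 had 36400, a mean of 36198.5 ± 285 (SD, n = 2), which covered 46.7 ± 0.169 Mb. The pooled replicates had 38375 peaks, of which 30331 formed the replicated set. The files gave no read counts, so the depth of each sample is unknown and no interval that needs it is given. Values of the replicated set come from 1 pooled list and have no replicates of their own, so means ± SD below are over the replicates' own lists, with n = 2.

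Cardiac transcription factors were among the genes under the widest stretches of H3K4me3 in the embryonic heart. The 20 widest domains, made by joining peaks up to 1000 bp apart, ran from 14606 to 25641 bp, while the domains at the start sites of all marked genes had a median of 2529 bp and a 95th percentile of 6015 bp. Of those 20, 7 lay over the cardiac transcription factors Hand2, Gata4, Nkx2-5, Gata6, Tbx5, Tbx20 and Tbx2, and 1 lay over Myh7, a myosin heavy chain of the contractile apparatus. The widest, over Hand2, a regulator of ventricle growth, spanned 25641 bp on chromosome 8 from 57311299 to 57336939 (mm10) and measured 21863.5 ± 5124 bp (SD, n = 2) in the replicates. It also held start sites of the non-coding genes Hand2os1, Gm34030 and 5033428I22Rik. Peaks of replicate 1 lay on both sides of a gap from 57329651 to 57330941, wider than the 1000 bp joined. Its Hand2 domain therefore counted as 18240 bp, against 25487 bp in replicate 2, though its peaks reached 57336903. The Nr2f2 domain (chromosome 7, 70345613 to 70370881) spanned 25269 bp and that of Gata4 (chromosome 14, 63229909 to 63253691) 23783 bp, with 21900 ± 1595 bp and 24777.5 ± 2498 bp (SD, n = 2) in the replicates. The Nkx2-5 domain (chromosome 17, 26835810 to 26854042) measured 18421.5 ± 329 bp, that of Gata6 16750.5 ± 196 bp and that of Tbx5 14310 ± 231 bp (SD, n = 2).

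**Figure D1:**
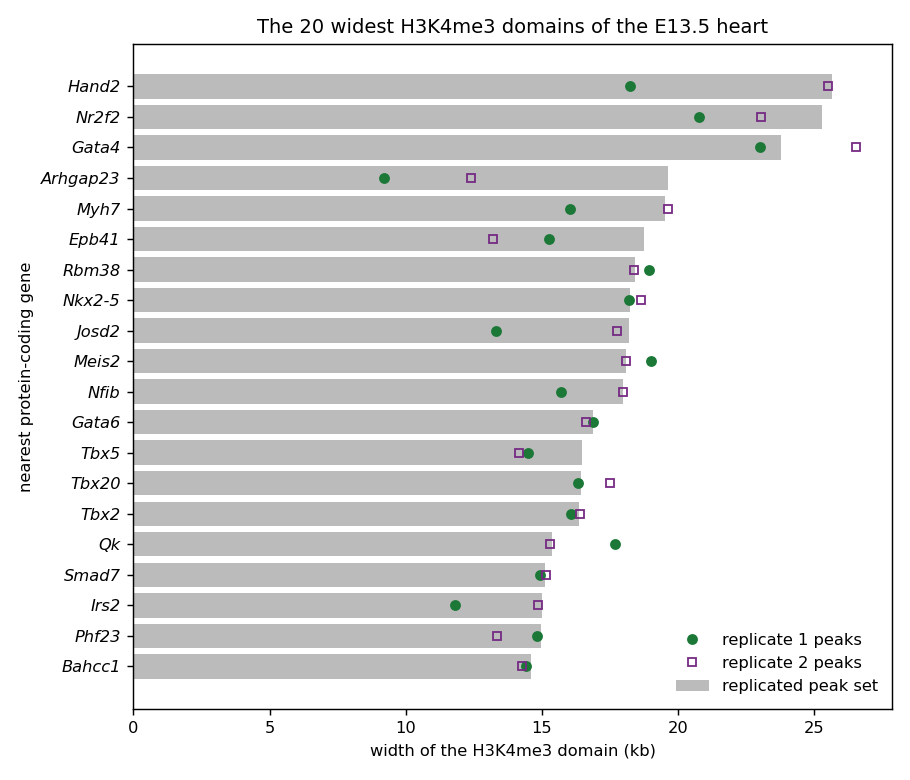
Width in kb of the 20 widest H3K4me3 domains of the replicated peak set (bars), by the nearest protein-coding gene. Points give the widest domain there joined from the peaks of each replicate, which a gap over 1000 bp cuts short. The bars run from 14606 bp at Bahcc1 to 25641 bp at Hand2, and 7 of the 20 lie over cardiac transcription factors.

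The other 12 of the 20 lay over Nr2f2, Arhgap23, Epb41, Rbm38, Josd2, Meis2, Nfib, Qk, Smad7, Irs2, Phf23 and Bahcc1. Nr2f2, Meis2 and Nfib encode transcription factors of many developing tissues, Smad7 an inhibitor of TGF-beta signalling and Irs2 an adaptor of the insulin receptor. The 3 that differed most between the replicated set and the replicates were Arhgap23 (19642 bp against 10804.5 ± 2266 bp), Epb41 (18762 bp against 14238 ± 1468 bp) and Hand2 (SD, n = 2). At Hand2 the difference came from the gap in replicate 1 given above, and widths of the replicates depend in this way on the joining limit. The Phf23 domain held the start sites of Dvl2 and Gabarap too, and that of Epb41 the start site of Gm10300.

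**Figure D2:**
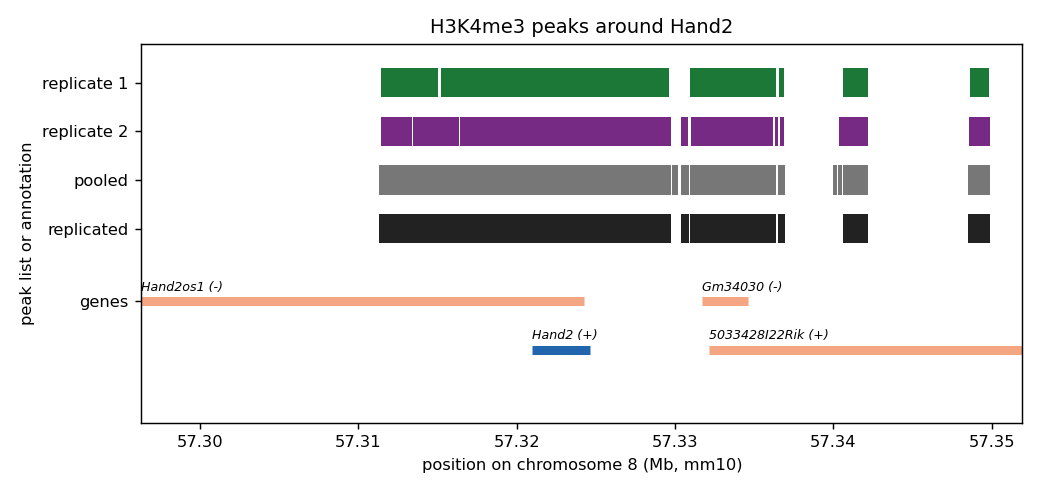
Peaks of each list around Hand2 on chromosome 8 (x axis, position in Mb, mm10) above the annotated genes, with the protein-coding gene in blue, non-coding genes in orange and the strand in brackets. The replicated domain runs from 57311299 to 57336939 and covers Hand2 and the start sites of 3 non-coding genes.

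Genes of heart muscle, endothelium and cushion mesenchyme carried the mark more often than other genes. A gene was called marked when a replicated peak lay within 1000 bp of a start site of one of its coding transcripts, which held for 14837 of 21829 protein-coding genes (68.0%). Marked were 24 of 25 sarcomere genes (Fisher's exact test, adjusted p = 0.00178), 29 of 30 cardiac transcription factors (exact, 0.000656), 24 of 25 genes of conduction and calcium handling (exact, 0.00178) and 16 of 16 natriuretic and secreted factors (exact, 0.00389). The same held for 29 of 30 endothelial and endocardial genes (exact, adjusted p = 0.000656) and 24 of 24 genes of fibroblasts and cushion mesenchyme (exact, 0.000656), the cells of valves and septa. The endothelial call was lost where only the 5'-most start site of each gene was used (exact, adjusted p = 0.0711). Myom2, Foxh1, Sln, which encodes sarcolipin of the atria, and Lyve1 of lymphatic vessels had no peak. Epicardial genes (14 of 15, adjusted p = 0.0592), smooth muscle and pericyte genes (12 of 14, 0.282) and erythroid genes (19 of 23, 0.210) did not pass Fisher's exact test against all other genes. Epicardial genes did pass without replicate 1 (exact, 0.00619) and without genes that have another coding start site within 5000 bp (exact, 0.0218). Erythroid genes did with a window of 2500 bp (exact, 0.0282). With peaks of a fold value of at least 5, 13 of 23 erythroid genes were marked (56.5% against 66.4% of other genes). With a window of 0 bp 15 were (65.2% against 66.2%). Of the 15 epicardial genes 12 (80% against 66.4%) and 11 (73.3% against 66.2%) were marked in these settings, with no call for either list. Msln of the epicardial list and Actg2 and Mylk of the smooth muscle list had no replicated peak.

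Against genes whose start sites had a like CpG content, sarcomere, erythroid, epicardial and smooth muscle genes stood out further than against all genes, and the other heart lists less. With genes in 10 equal bins of the CpG observed/expected ratio, the share marked ran from 2.24% in the lowest bin to 99.7% in the highest. CpG-matched genes gave an expected 42.9% for the sarcomere list, against 96.0% observed (permutation test, adjusted p = 0.0009), and 36.2% for the erythroid list, against 82.6% (permutation, 0.0009). Endothelial genes (96.7% against 69.0%), fibroblast and cushion genes (100% against 69.9%), epicardial genes (93.3% against 62.3%) and smooth muscle and pericyte genes (85.7% against 57.7%) were also higher (permutation tests, adjusted p = 0.0009, 0.0009, 0.00386 and 0.0441). So were genes of conduction and calcium handling (against 80.7%) and the natriuretic and secreted factors (against 79.4%), with adjusted p of 0.00945 and 0.0204 in the permutation test. The cardiac transcription factors (96.7% against 93.4%) no longer differed (permutation test, adjusted p = 1), as nearly every gene of their CpG content was marked. These matched comparisons used all replicated peaks and the window of 1000 bp, so they count weak peaks and peaks beside the start site.

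Genes of the other cell types listed differed in how often they carried the mark. Not all of these are foreign to the heart, as the neural crest list stands for cells of the outflow tract and of nerves. Immune, liver, skeletal muscle, skin and germ cell genes were marked less often than other genes: 4 of 24 macrophage and leukocyte genes (Fisher's exact test, adjusted p = 1.7e-06), 6 of 24 hepatocyte genes (exact, 8.7e-05), 9 of 23 skeletal muscle genes (exact, 0.00777), 5 of 16 epidermis genes (exact, 0.00695) and 4 of 24 germline genes (exact, 1.7e-06). Without a peak were Adgre1, Cd3e and Cd19 of immune cells, Alb, Afp and Apob of the liver, Myf5, Myh1 and Chrna1 of skeletal muscle, Krt1, Ivl and Flg of skin and Figla, Gdf9 and Mael of germ cells. Of the 1417 olfactory and vomeronasal receptor genes, 4 were marked, and the list was lower by Fisher's exact test. Regulators of the central nervous system, in contrast, were marked at 34 of 35 genes (exact, adjusted p = 0.000129) and neuronal function genes at 18 of 20 (exact, 0.0417). Neural crest and Schwann precursor genes (11 of 15, adjusted p = 0.787), lung and foregut genes (9 of 16, 0.437) and pluripotency genes (10 of 18, 0.337) did not differ from other genes in Fisher's exact test. Pou5f1, the central pluripotency factor, had no peak, nor did Phox2b, Th and Dbh of sympathetic neurons or Sftpb and Scgb1a1 of the lung.

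**Figure D3:**
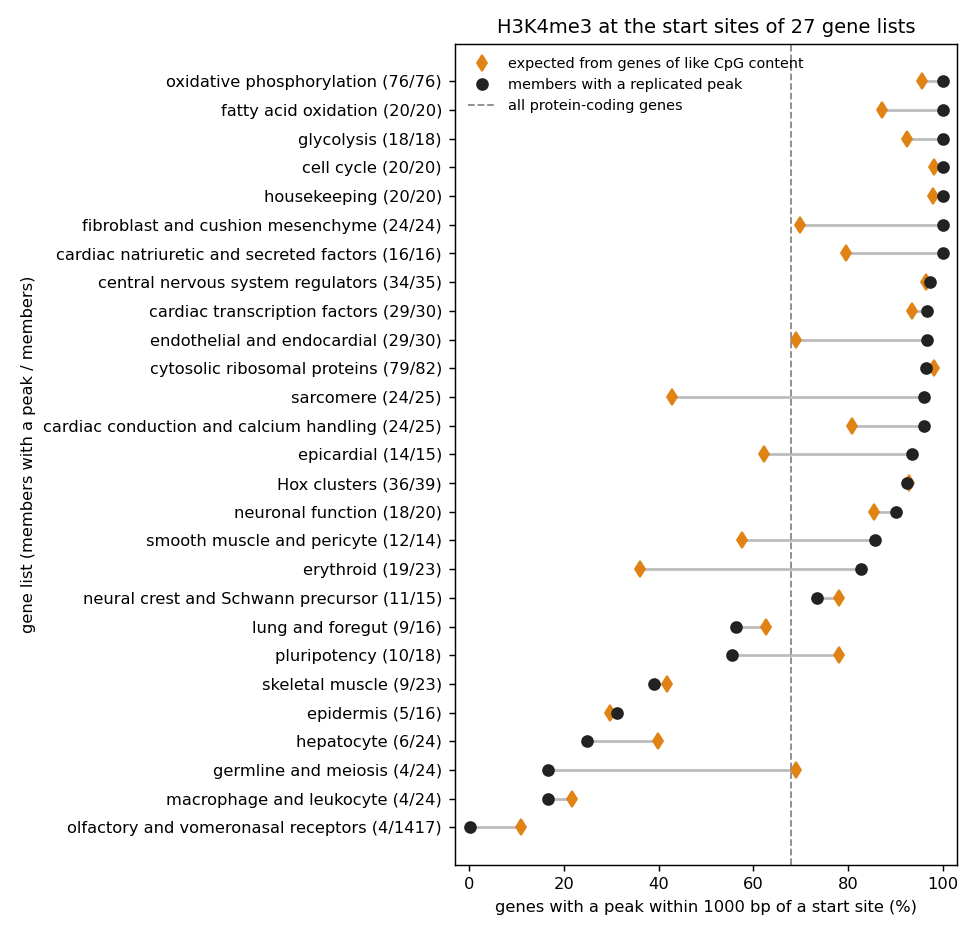
Percent of each list's genes with a replicated H3K4me3 peak within 1000 bp of a start site (black points), with the percent expected from genes of like CpG content (orange) and the 68.0% of all protein-coding genes (dashed line). Sarcomere genes lie at 96.0% against 42.9% expected and germline genes at 16.7% against 69.1% expected.

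CpG content matched the low share in some of these lists and not in others. Germline genes stayed lower than genes of like CpG content (16.7% against 69.1%; permutation test, adjusted p = 0.0009), as did the receptors (0.282% against 11.03%; permutation, 0.0009), and pluripotency genes became lower (55.6% against 78.0%; permutation, 0.0275). Macrophage and leukocyte genes (16.7% against 21.8%), hepatocyte genes (25% against 39.9%), skeletal muscle genes (39.1% against 41.9%) and epidermis genes (31.2% against 29.8%) no longer differed (permutation tests, adjusted p = 1, 0.142, 1 and 1). Neither did the neural lists, at 97.1% against 96.3% for the regulators and 90% against 85.4% for neuronal function (permutation tests, adjusted p = 1 for both). The neuronal function list also lost its call with the peaks of either replicate alone (Fisher's exact test, adjusted p = 0.0627 without replicate 1 and 0.0628 without replicate 2; 0.0346 to 1 over all settings tried). A marked gene can carry a neighbour's peak: Apoh, Foxa3, Mylpf and Actn3, 4 of the wider members of the hepatocyte and skeletal muscle lists, each had another coding gene's start site within 1000 bp, at Prkca, Sympk, Tbc1d10b and Zdhhc24.

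Genes of the housekeeping, cell cycle, energy metabolism and ribosomal protein lists were marked almost without exception. All 20 housekeeping genes, 20 cell cycle genes and 20 genes of fatty acid oxidation were marked (Fisher's exact test, adjusted p = 0.00104 for each), as were 18 of 18 glycolysis genes (exact, 0.00239), 76 of 76 genes of oxidative phosphorylation (exact, 3.7e-12) and 79 of 82 cytosolic ribosomal protein genes (exact, 2.2e-09). The 3 ribosomal genes without a peak were Rpl10l, Rpl39l and Rpl3l, paralogs of the common forms. Of the genes in the Hox clusters, which set position along the body axis, 36 of 39 were marked (exact, adjusted p = 0.00104). The Hox call was lost with peaks of a fold value of at least 5 (exact, adjusted p = 0.112) and the glycolysis call with the 5'-most start site (exact, 0.0637). Against genes of like CpG content only oxidative phosphorylation among these 7 lists stayed higher, at 100% against 95.5% (permutation test, adjusted p = 0.0339). Fatty acid oxidation had 100% against 87.0% (permutation, adjusted p = 0.0698). All 15 lists called higher lay above the 68.0% of all genes, and all 6 called lower lay below it, in the peaks of both replicates.

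Cardiac transcription factors and sarcomere genes had the widest domains of the 24 lists. The median width was 8691 bp at the cardiac transcription factors and 6646.5 bp at sarcomere genes, against about 2530 bp in random lists of marked genes (permutation tests, adjusted p = 0.0008 for both, from the smallest unadjusted p the random lists allow). In the replicates these medians were 8177 ± 726 bp and 6563 ± 8.84 bp (SD, n = 2). Among sarcomere genes Myh7 had 19511 bp (17833.5 ± 2534 bp in the replicates), Actc1, the cardiac actin, 11227 bp (10987 ± 225), Myh6 10979 bp (11129 ± 161) and Tpm1 10729 bp (10532.5 ± 211; SD, n = 2). Genes of conduction and calcium handling had a median of 4467.5 bp (permutation, adjusted p = 0.0008), with 14304 bp at Slc8a1, the sodium-calcium exchanger, 9453 bp at Gja1, 8631 bp at Atp2a2, the calcium pump of the sarcoplasmic reticulum, and 8454 bp at its regulator Pln. Natriuretic and secreted factors had a median of 4300.5 bp (permutation, adjusted p = 0.0012), led by Bmp7, Fgf9, Vegfa and Wnt11. Nppa, the gene of atrial natriuretic peptide, had a domain of 2469 bp (2115.5 ± 301 bp in the replicates; SD, n = 2) and a fold value of 8.08, while all marked genes had a median fold value of 54.0.

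Of the lists of non-muscle heart cells, the endothelial and the fibroblast and cushion lists were wide under all settings tried. Endothelial and endocardial genes had a median of 4513 bp and fibroblast and cushion genes one of 4766 bp (permutation tests, adjusted p = 0.0008 for both). Nfatc1 and Npr3, markers of the endocardium, had 9453 bp and 9175 bp, and Pdgfra, Twist1, Sox9 and Prrx1 of the mesenchyme had 9848, 7482, 7101 and 6818 bp. In the epicardial list the median of 2383.5 bp did not differ from random lists (permutation test, adjusted p = 0.697), although Wt1 had 12348 bp (12152 ± 124 bp in the replicates), Tcf21 8882 bp and Tbx18 7123 bp (SD, n = 2). Smooth muscle and pericyte genes had a median of 2959.5 bp (permutation, adjusted p = 0.438), and were wider than random lists only where those were matched on CpG content (permutation, 0.0312). Erythroid genes had a median of 3614 bp (permutation, adjusted p = 0.0258), with 13690 bp at Tal1, which the endothelial list holds too, and 10420 bp at Slc4a1, the anion exchanger of red cells. That call was lost without replicate 1, where the median lay 419 bp above random lists (permutation, adjusted p = 0.277; 0.00213 to 0.540 over all settings tried), and in the replicates the erythroid median was 3293 ± 623 bp (SD, n = 2).

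**Figure D4:**
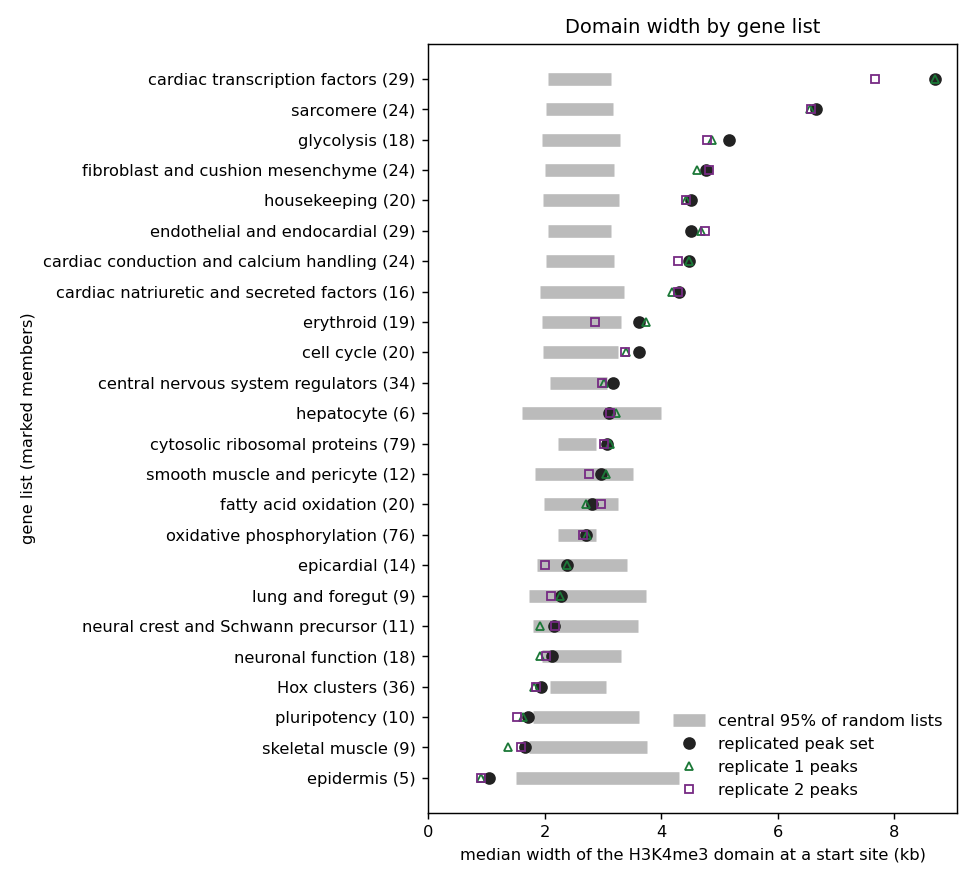
Median width in kb of the H3K4me3 domain at the start sites of each list's marked genes, in the replicated set (black) and in each replicate (open symbols), over the central 95% of 10000 random lists of marked genes (grey bars). Cardiac transcription factors (8691 bp) and sarcomere genes (6646.5 bp) lie farthest to the right of the bars, and Hox clusters (1932.5 bp), pluripotency (1717.5 bp), skeletal muscle (1663 bp) and epidermis (1038 bp) to their left.

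Among the lists that stand for no single cell type, domains were wide at glycolysis genes (median 5167.5 bp, permutation test, adjusted p = 0.0008) and housekeeping genes (4516.5 bp, permutation, 0.0012). So were those at cell cycle genes (3611 bp, permutation, 0.0152, and 0.0836 where peaks were joined across 3000 bp). Hk1 had 11060 bp, Slc2a1, a glucose transporter, 9062 bp, Ccnd2 8250 bp and Actb 6194 bp (5948.5 ± 16.3 bp in the replicates; SD, n = 2), while the 13750 bp of Eno3 included the start site of Pfn1. Ribosomal protein genes had a median of 3064 bp (permutation, adjusted p = 0.00693), which did not pass the threshold against CpG-matched lists (permutation, 0.213) or without close neighbours (permutation, 0.0851). Fatty acid oxidation (2816.5 bp) and oxidative phosphorylation (2707.5 bp) did not differ from random lists (permutation tests, adjusted p = 0.438 and 0.409). Central nervous system regulators had a median of 3168 bp (permutation, adjusted p = 0.0381), led by Dlx2 with 6749 bp, but the call was lost in each replicate alone (permutation, 0.0650 without replicate 1 and 0.0596 without replicate 2; 0.0008 to 0.922 over all settings tried, with the difference turned where peaks were not joined). Hox genes had narrower domains (1932.5 bp; permutation, adjusted p = 0.0122), apart from the 14421 bp stretch that Hoxa1 and Hoxa2 shared, and so had the 5 marked epidermis genes (1038 bp; permutation, 0.0110). The Hox call was lost with pooled peaks (permutation, adjusted p = 0.154) and turned where peaks were joined across 3000 bp (permutation, 0.594), and the epidermis call was lost against CpG-matched lists (permutation, 0.217).

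No difference in width from random lists was called for neural crest (2163 bp), neuronal function (2115.5 bp), hepatocyte (3097 bp), lung and foregut (2282 bp), skeletal muscle (1663 bp) or pluripotency genes (1717.5 bp). Their adjusted p in the permutation test were 0.438, 0.247, 0.438, 0.628, 0.0501 and 0.0501. Pluripotency genes were narrower than CpG-matched lists (permutation, adjusted p = 0.0329) and than random lists in each replicate alone (permutation, 0.0261 without replicate 1 and 0.0481 without replicate 2), and skeletal muscle genes were narrower without replicate 2 (permutation, 0.0115). Tbx3, which the cardiac list holds too, had the widest domain of the pluripotency list at 9260 bp. The widest stretches in the neural crest list were at Tfap2a (8314 bp) and Ednrb (6572 bp), and in the lung and foregut list at Foxa2 (6110 bp) and Foxa1 (5365 bp). The macrophage and leukocyte, germline and receptor lists had fewer than 5 marked members and were not tested for width. Genes are not independent replicates, so each p sets a list against other genes of these 2 samples and says nothing about other hearts.

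The genes with the highest fold values were not those with the widest domains. The 10 highest fold values at start sites were those of Atxn2l (88.7), Eif4a1, a translation initiation factor (85.5), Actg1, a cytoplasmic actin (84.7), Vamp2 (84.1), the shared start of Mocs3 and Dpm1 (83.9), Ccnl2 (83.6), Dync1h1, a heavy chain of dynein (83.4), Hnrnpu (83.3) and Dnajc8 (83.3). In the replicates Atxn2l had 76.5 ± 0.781 and Eif4a1 76.1 ± 0.816 (SD, n = 2). Their domains, from 2751 bp at Dync1h1 to 7164 bp at Dnajc8, were all narrower than the 20 widest.

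Most of the strong signal lay at start sites, and the weaker peaks lay away from them. Of the 30319 replicated peaks on the chromosomes used, 15353 (50.6%) lay within 1000 bp of the start of a coding transcript, against a mean of 4.41% and a highest value of 4.60% in 100 shuffles (one-sided permutation test, p = 0.0099, the smallest the shuffles allow). In the replicates the share was 44.8% ± 0.427 (SD, n = 2). A further 8.81% lay at the starts of other transcripts, 18.9% in introns, 17.6% between genes and 2.23% in coding sequence. Median fold values were 49.8 at coding start sites, 8.28 at other starts, 5.93 between genes and 4.14 in introns, and median widths 2226 bp at coding start sites and 577 bp in introns. Peaks more than 10000 bp from any annotated start numbered 5396 (17.8%), with a median fold value of 5.17.

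Some distant peaks were as strong as those at promoters. The 5 with the highest fold value lay 32332 bp from Pum2 (chromosome 12, 8640108 to 8641802; 59.4 ± 2.90 in the replicates), nearest to the non-coding gene Lncppara (chromosome 15, 85669386 to 85674697; 58.6 ± 4.42), nearest to Gm47110 (chromosome 9, 67631602 to 67635068; 58.2 ± 0.308), nearest to Gm47481 (chromosome 9, 32031367 to 32034392; 56.9 ± 2.07) and within Tns3 (chromosome 11, 8623084 to 8625480; 55.0 ± 1.58; fold values, SD, n = 2). A second annotation, RefSeq, places a transcript start inside 3 of these 5, of Tln2, Arhgap32 and Tns3.

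The replicates shared most of their peaks, and those they did not share were weak. Of replicate 1's peaks 81.2% (29205 of 35986) were covered over at least 50% of their length by peaks of replicate 2, and of replicate 2's peaks 80.1% (29138 of 36387) by those of replicate 1. Shuffled peaks gave a mean of 1.76% in both directions and at most 1.96% and 1.93% (one-sided permutation tests, p = 0.0099, the smallest the shuffles allow). Unshared peaks had a median fold value of 2.93 in replicate 1 and 2.995 in replicate 2, against 16.1 and 18.2 for shared ones, and lay at coding start sites in 11.9% and 10.2% of cases, against 52.8% and 53.1%. At the level of genes, 14769 were marked in both replicates, 94 in replicate 1 only, 112 in replicate 2 only and 6854 in neither. Across the genes marked in both, which are not independent replicates, log2 fold values correlated with Pearson's r = 0.927 and Spearman's rho = 0.759, and log2 domain widths with r = 0.947 and rho = 0.947.

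Of the 24 lists compared between the replicates, the erythroid list alone stood apart, with lower values in replicate 2. The fold value is computed within each list of peaks, so its ratio between lists depends on the depth and control of each, and the ratio was centred on its median over all genes (0.13 on the log2 scale). Of 19 erythroid genes marked in both replicates 16 were lower in replicate 2 than the median gene, and their median log2 ratio was -0.31, at percentile 0.03 of random lists of like fold value. Chance alone puts 1.2 of 24 lists outside the central 95%. Tal1 had a centred log2 ratio of -1.06, the embryonic globin gene Hba-x -0.76, Slc4a1 -0.63 and Gata1, the main erythroid transcription factor, -0.50. Apart from Tal1 (fold values 35.2 and 18.5 in replicates 1 and 2) these were weak peaks. Hba-x had 5.19 and 3.34, Slc4a1 7.04 and 4.99 and Gata1 5.19 and 4.01. Kel, which encodes the Kell blood group protein and belongs to no list, was among the 5 lowest of all genes with -1.45. Rhag was marked in replicate 1 only and Hba-a1 in replicate 2 only, and the adult globin genes are near-identical copies, so their peaks are uncertain. The list lay inside the central 95% where peaks had to reach a fold value of 5 (12 genes, -0.12, percentile 8.06) or to cover the start site (10 genes, -0.07, percentile 19.1).

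Domain widths set the erythroid list apart by more, in a comparison added after the data were examined. The median width of the 19 genes was 3818 bp in replicate 1 and 3078 bp in replicate 2, with a median log2 ratio of -0.47 below all 10000 random lists, and 17 of 19 were narrower in replicate 2. These random lists were matched on mean width and not on fold value. The 19 genes had a median fold value of only 9.92 in replicate 1, so the percentile does not hold peak strength constant. The exceptions were Tal1 (12801 and 13498 bp in replicates 1 and 2) and Slc4a1 (10239 and 10867 bp), both named above for lower fold values. Hox genes (0.20), central nervous system regulators (0.07) and lung and foregut genes (0.13) lay above the central 95% by width, each by less. The sarcomere (log2 fold ratio 0.08), cardiac transcription factor (0.01), and endothelial (0.04) lists lay inside the central 95% of random lists by both measures, as did the epicardial list (0.11), which lay above it for fold value times width (0.27, percentile 98.5). These values describe 2 libraries and have no replicate check, and whether their embryos were collected separately is not stated.

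**Figure D5:**
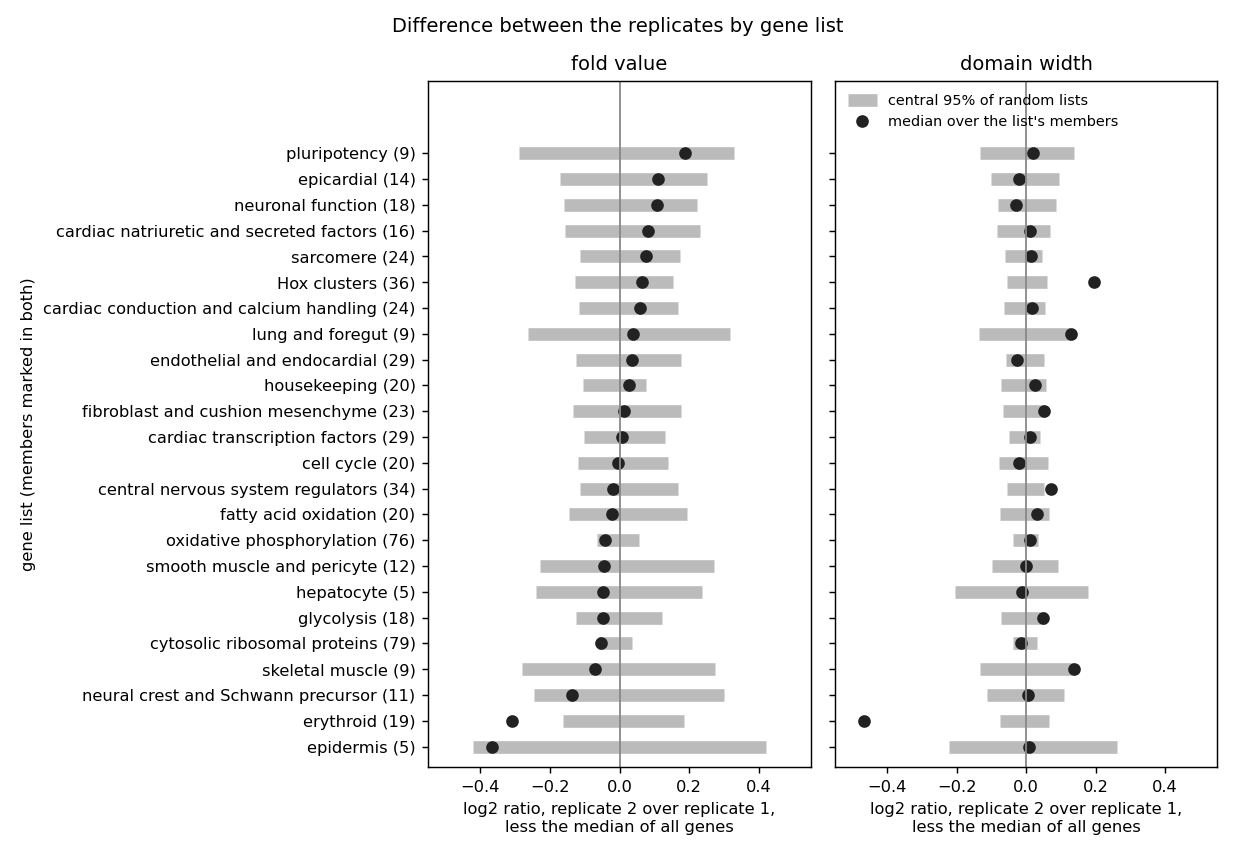
Median log2 ratio of replicate 2 over replicate 1 for each list, less the median of all genes, for fold values (left) and domain widths (right), over the central 95% of 10000 random lists (grey bars). The random lists were matched on mean fold value on the left and on mean width on the right. The erythroid list lies below the bars at -0.31 by fold value and at -0.47 by width.

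Few list members changed calls between the replicates. At most 4 members of a list were marked in 1 replicate only, too few for an exact McNemar test to pass the threshold, and 0 of 27 lists did, with 0 at an unadjusted p under 0.05. Among the immune genes Spi1 and Tyrobp were marked in replicate 1 only and Csf1r and C1qa in replicate 2 only, and the Hox genes Hoxc6 and Hoxd12 in replicate 1 only and Hoxc11 in replicate 2 only. The largest single differences were those of Nup160 (centred log2 ratio -3.95), Nkx2-1 (-1.49), Kel, Anxa1 (-1.44) and Tmem267 (-1.43), lower in replicate 2, and of Bricd5 (4.25), Hspb9 (3.25), Sost (3.04), Rhof (2.28) and Gdf15 (1.82), higher in replicate 2. Domain widths at the more extreme of these barely moved, with 2947 ± 9.90 bp at Nup160 and 3693.5 ± 98.3 bp at Bricd5 (SD, n = 2). A fold value is that of the highest single peak within 1000 bp of a start site, so these ratios do not show a change over the whole domain. Bricd5, Hspb9, Tmem267 and Kel also lay 3492, 1385, 344 and 3561 bp from another coding gene's start site.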

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

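Of the replicated peaks, 12 lay on 7 sequences of the assembly that are not placed on a chromosome, and these stand here because no comparison of genes used them. Their fold values ran from 2.55 to 46.2 with a median of 12.4, and the replicates had 11 and 13 peaks on such sequences.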

How the results depend on the processing

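Settings added after the data were examined were the removal of genes with another coding start site within 5000 bp, the matching on fold value and CpG content together, and the domain widths in the replicate comparison. The overlap of the replicates and the share of peaks at coding start sites stayed above every shuffle under all settings tried, with 73.9% to 95.6% of replicate 1's peaks and 73.1% to 93.2% of replicate 2's peaks shared and 42.0% to 65.3% of peaks at coding start sites. The number of genes marked ran from 14258 to 15052. Of the lists, 9 were marked more often and 3 less often against a background matched on CpG content, where 15 and 6 were called against all genes. The matching moved the expected share, for example from 67.9% to 93.4% for cardiac transcription factors and from 68.0% to 21.8% for macrophage and leukocyte genes. This setting also replaces Fisher's exact test by a permutation test, and how much that adds was not tested. Against the matched background the differences of epidermis (1.497 percentage points), Hox clusters (-0.458) and ribosomal protein genes (-1.81) turned, and none of these 3 passed the threshold. Under the other settings 12 to 16 lists were marked more often and 6 less often. Lists with wider domains numbered 10 to 12. Lists with narrower domains numbered 2 as planned, 3 with a fold value of at least 5, with pooled peaks and with peaks not joined, 1 with a window of 0 bp, where epidermis had fewer than 5 members left, 5 with a window of 2500 bp and 4 to 5 where 1 replicate was left out. Macrophage and leukocyte genes (without either replicate) and the receptors (2500 bp) then had enough marked members to be tested, and pluripotency genes in all 3 cases and skeletal muscle genes (2500 bp, without replicate 2) gained a call, for which the cause was not tested. Pluripotency genes also gained it with pooled peaks, the 5'-most start site, peaks joined across 3000 bp and CpG-matched lists, and skeletal muscle genes with a fold value of at least 5 and peaks not joined. The median width of central nervous system regulators lay 31 bp below that of random lists (-31) where peaks were not joined, and that of Hox clusters 182.5 bp above it where peaks were joined across 3000 bp, and in neither case was the threshold passed. The wider reach of a joined domain in a gene cluster follows from the setting. Between the replicates 1 list lay outside the central 95% in the comparison as planned. That list was the erythroid one, which lay inside with a fold value of at least 5, where epidermis lay outside. The number was 0 with a window of 0 bp, where 10 erythroid genes were left, 3 with fold value times width (erythroid, epicardial and Hox clusters), 2 with ranks of fold value, 2 without close neighbours and 4 with domain width, and the cause was not tested. Among single lists 33 results lost their call and 19 gained one, and 386 values without a test, most of them widths of single domains, moved by more than the spread between replicates, or for a count by more than 1.5 times. No paired analysis was possible because there is 1 group. The unknown depth limits the weak peaks: a gene without a peak is one where none was called, and not one shown to lack the mark.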

Other observations

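The tests on domain widths of erythroid genes and on neural tissue, and the matching on CpG content and fold value together, were chosen after the related results were seen. Long non-coding RNA genes near the start sites of coding genes were called marked more often than those farther away, a difference that was not tested. The coding gene's own peak can mark such a neighbour, and 68.0% of coding genes were marked. The higher share near them was therefore largely set by the grouping and does not show a mark of the non-coding genes themselves. Of 2721 long non-coding RNA genes with a start site within 5000 bp of a coding one, 1945 (71.5%) were marked with a median domain of 2828 bp, and of the 7434 farther away 967 (13.0%) with a median of 1177 bp. Among the latter, Malat1 had a domain of 11103 bp (10799 ± 407 bp; SD, n = 2) and Neat1, which builds nuclear paraspeckles, one of 9627 bp (9797 ± 537 bp). The imprinted genes H19 and Meg3 had 4075 bp (3846 ± 305 bp) and 3256 bp (3321 ± 404 bp; SD, n = 2).

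Genes of both sex chromosomes carried the mark, in pools that hold both sexes per the labels. Xist, the RNA that silences an X chromosome in females, had a domain of 3928 bp (3830.5 ± 41.7 bp; SD, n = 2), and on the Y chromosome 4 of 183 protein-coding genes were marked, Kdm5d, Uty, Ddx3y and Eif2s3y. On the X chromosome 508 of 948 genes (53.6%) were marked, and on the autosomes 14325 of 20698 (69.2%). Of the 4 marked olfactory and vomeronasal receptor genes, Vmn1r4 lay 90 bp from the start site of Nt5c3, with a domain of 8373 bp, Olfr94 4119 bp from Ubd, and Olfr1033 and Olfr658 had narrow peaks of 421 bp and 384 bp with the nearest other coding start, that of another receptor, more than 5000 bp away.

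Erythroid genes had lower fold values in replicate 2 (median centred log2 ratio -0.31, 16 of 19 genes), while sarcomere genes had a median of 0.08. CpG content does not account for this, as the list stayed at percentile 0.07 among lists matched on CpG content and fold value together, while the height or splitting of single peaks stays open: fold value times width summed over the domain put the list at percentile 0, but the bound set for this test was wrong, since the widths alone were lower (-0.47). A candidate explanation is more red blood cells in the pool of replicate 1, and the added list of erythroid genes pointed 2 ways: by fold value it lay at percentile 32.3, with 16 of 27 genes lower in replicate 2, and by domain width at percentile 0, with 21 of 27 narrower and a median log2 ratio of -0.31. The added genes had a median fold value of 42.4 in replicate 1, against 9.92 for the erythroid list, so the fold value test was made on stronger peaks. Whether this bears on its result was not tested. The width test matched its random lists on mean width and not on fold value, so it does not hold peak strength constant. The globin genes Hba-x and Hbb-y had fold values of 5.19 and 6.32 in replicate 1 and of 3.34 and 5.57 in replicate 2. Whether the replicates' embryos were collected separately, which more blood cells would need, is not stated. Of other weakly marked lists, Hox clusters (median log2 width ratio 0.20), skeletal muscle (0.14) and lung and foregut (0.13) were wider in replicate 2. So were central nervous system regulators (0.07). Neuronal function (-0.03), epicardial (-0.02) and endothelial lists (-0.02) went the other way, inside the central 95% of random lists. These values argue against a calling difference common to weakly marked lists. A calling difference confined to erythroid genes and more blood cells cannot be told apart.

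Strong peaks far from annotated start sites numbered 504, those with a fold value of at least 20 more than 10000 bp away. Repetitive sequence does not account for them as a set, as repeat-masked bases made up a median of 11.04% of them and 9.14% of the weaker distant peaks. A median cannot exclude it for a part of them. The peak of highest fold value, 32332 bp from Pum2, had 53.5% repeat-masked bases, and the other strongest ones named above had 9.51% to 15.9%. Start sites missing from the annotation may account for a part of the 504 peaks. Of these, 20.0% (Wilson 95% interval 16.8% to 23.8%) lay within 1000 bp of a RefSeq transcript start. Among the weaker distant peaks, which were narrower, the share was 7.65%. It was 6.25% on average and at most 8.53% in 100 shuffles of the 504 peaks. The shuffles placed them anywhere on their chromosome, not only far from annotated starts. CpG-rich sequence, with an observed/expected ratio of at least 0.6, made up 29.2% (25.4% to 33.3%) of the 504 peaks and 8.12% of the weaker ones, so it too leaves the larger part open. No biological explanation was tested.

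Central nervous system regulators were marked at 34 of 35 genes, yet their median fold value was 20.5 (18.8 and 17.4 in the replicates), against 54.0 for all marked genes. Their CpG content does not account for this, since CpG-matched marked genes had a median of 56.5 and the list lay at percentile 0. Hox clusters (10.6), pluripotency (12.4), neural crest (19.3), neuronal function (21.6), lung and foregut (27.5), erythroid (9.47) and skeletal muscle genes (9.73) were low as well against CpG-matched genes (permutation tests, adjusted p = 0.0012, 0.0012, 0.00192, 0.0012, 0.0024, 0.00853 and 0.0396). Neural tissue in the dissected pools would be expected to widen the domains of neuronal function genes, which lay at percentile 19.6 of CpG-matched lists, and a small share of such cells is not excluded by this. A weak mark in many cells and a strong mark in few cells cannot be told apart from these peak lists, and no biological explanation was tested.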
